A study of Oryza sativa with 12 samples.

How the data were processed

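Flag leaves of rice plants at 10 weeks of age were profiled on 12 Affymetrix rice arrays, 1 array per biological replicate. The labels name 2 genotypes, wild type and plants carrying PSARK::IPT, a senescence-associated promoter driving the cytokinin synthesis enzyme isopentenyltransferase. They also name 2 water conditions, watered and 3 days without water. Each of the 4 groups, written here WT_watered, WT_stressed, IPT_watered and IPT_stressed, held 3 arrays. Groups and replicate numbers came from the labels alone.

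The deposited values were on a log2 scale and had been made with RMA by the authors, per the submitters' processing notes; RMA corrects background, normalizes between arrays and summarises the probes of a probe set. The software and version used for it were not given in the sources used here. The deposited table held 57381 probe sets, of which 123 control probe sets and 64 reporter probe sets for foreign sequences were kept out of the tests and used as checks. The remaining 57194 were tested. The values were used as deposited, with no filter and no further normalization. The means of all tested probe sets were nearly equal between arrays (4.16 in every group), whereas the standard deviations over probe sets ran from 1.95 in WT_stressed to 2.21 in IPT_stressed.

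Probe sets were named through the array annotation supplied with the data, whose gene identifiers were looked up in a table of the RefSeq rice assembly ASM3414082v1, used for names only. Of the tested probe sets 22436 were tied to exactly 1 gene, 95 to several and 34663 to none listed. The probe sets with 1 gene covered 17905 genes, of which 2459 had a protein name or symbol other than a locus number. Where a gene had several probe sets, the one with the highest mean over all 12 arrays stood for it.

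Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). One mean was fitted per group over all 12 arrays, so that the groups shared one estimate of the spread. The 5 contrasts were the stress effect within each labelled genotype, the labelled genotype effect within each water condition, and the difference of the 2 stress effects. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05, and the number with a change of at least 2-fold was counted too. Errors of changes are limma's moderated standard errors, and errors of group means are standard deviations over 3 arrays. Besides limma's test, an exact test of 3 arrays against 3 cannot give a two-sided p under 0.1; the number of arrays limits the precision. No detection calls were used. The 95th percentile of the group means of 106 probe sets for foreign sequences (reporters and unspiked bacterial controls) served as the background level: 3.62 in WT_watered, 4.10 in WT_stressed, 3.15 in IPT_watered and 3.34 in IPT_stressed. The reporters judged against this level below were among the 106, which can raise it in groups where they read high. Where only the dimmer group lay at background, the fold was computed against that level and is given as a lower bound. No fold is given where both groups lay there.

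The comparisons, the model, the alternatives, the rule for named genes and the gene lists were chosen before the data were examined. Named genes were, per comparison, the 10 largest rises and 10 largest falls among called genes with a protein name and non-overlapping arrays, and up to 4 members of each list with the smallest adjusted p. For the difference of the stress effects, where no gene passed, they were the 5 genes with the smallest p. The lists covered cytokinin metabolism, type-A response regulators, ABA metabolism and PP2C, LEA and dehydrin, drought regulators, brassinosteroid, jasmonate, gibberellin, ethylene synthesis, photosynthesis, chlorophyll synthesis, chlorophyll breakdown and senescence, nitrogen assimilation, sucrose and starch, antioxidant enzymes, aquaporins, heat shock, circadian clock, flowering regulators, cell wall loosening, cytosolic and plastid ribosomal proteins, WRKY factors, NAC factors, auxin response, pathogenesis related, diterpenoid phytoalexin, dividing cell markers, and 2 lists for other tissues, panicle and floral organ markers and anther markers. Of 263 loci fixed by number, 162 were matched through aliases, 97 had no alias in the table and 4 were dropped because the alias lay on another chromosome. The annotation gave symbols rather than descriptive text, so the text patterns of the lists were replaced by symbol stems, chosen after the annotation had been seen; they added 312 genes. A further 3 genes whose other alias named another protein family were dropped, as the fixed rule required, but only after a first run of the list tests, and the drop changed no call. The lists then held 468 different genes. The plastid ribosomal list had 0 members on the array and was not tested, which left 29 lists.

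Lists were tested with camera from limma at its preset correlation of 0.01 over the 17905 genes, with Benjamini-Hochberg adjustment over the 29 lists within a comparison. Camera asks whether a list lies above or below the other genes, which need not be the sign of its median. The other genes were not matched to the list on signal level. Camera with an estimated correlation and fry were alternatives. The fit was also repeated with the replicate number as a block, with a minimum mean log2 value of 5, quantile normalization, equal array medians, limma's trend and robust options, array weights, leaving out probe sets marked _x_at and _s_at, 1 probe set per gene, the mean of a gene's probe sets, fitting only the groups compared, and leaving out each array in turn. One further fit, with the difference between the 3' and 5' GAPDH probe sets as a covariate, was added after the data had been seen. A scan of 84 gene families, defined by symbol stems shared by at least 6 genes, was also added then.

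The replicate numbers were checked for pairing: of 18 pairs of arrays with the same number in different groups, 9 had a correlation of deviations from the group means above 0.1 (range -0.10 to 0.19), so the numbers were not treated as pairs. Pairs of arrays correlated at 0.908 to 0.994 over probe sets and 0 array columns were identical. The fit was tested on simulated data with 200 of 57194 probe sets changed, in equal shares by 2-fold and by 4-fold. It recovered 57% of the 2-fold and 96% of the 4-fold changes for the stress effect in wild type, and 56% and 96% for PSARK::IPT. For the genotype effect it recovered 63% and 98% when watered and 65% and 97% under stress. For the difference of the stress effects it recovered 19% and 88%. False calls numbered 5 to 9. The noise was drawn independently for each probe set. The real genotype comparisons called 10981 and 26357 probe sets, so these rates need not hold there.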

Results

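Transcript levels were measured in flag leaves of wild-type rice and of rice carrying PSARK::IPT, in which a promoter active in ageing leaves drives a cytokinin synthesis enzyme, each watered or left without water for 3 days. There were 3 arrays in each of the 4 labelled groups. All values are log2 RMA values, and n is 3 arrays per group throughout. The labels call the replicates biological.

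The reporter probe sets, which match foreign sequences such as those used in transformation constructs, were examined first as a check of the labels. The reporter RPTR-Os-K01193-1_at read 8.98 ± 0.24 (SD, n = 3) on the arrays labelled WT_stressed and 10.16 ± 0.27 on those labelled IPT_stressed. It read 2.08 ± 0.08 on the arrays labelled IPT_watered, below the background level of 3.15, and 3.48 ± 2.21 on those labelled WT_watered, where replicate 3 alone read 6.03. The reporter RPTR-Os-AF292559-4_s_at read 7.68 ± 0.60, 7.97 ± 0.46, 2.11 ± 0.13 and 2.61 ± 0.60 on the same groups in that order. These reporters therefore followed the labelled water condition and not the labelled genotype. The sources used here do not say whether the PSARK::IPT plants carry these sequences; if they mark transgenic plants, their signal goes against the labels. Every group below is therefore the group as labelled, and every direction between genotypes or water conditions rests on labels that this check leaves in doubt.

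**Figure D1:**
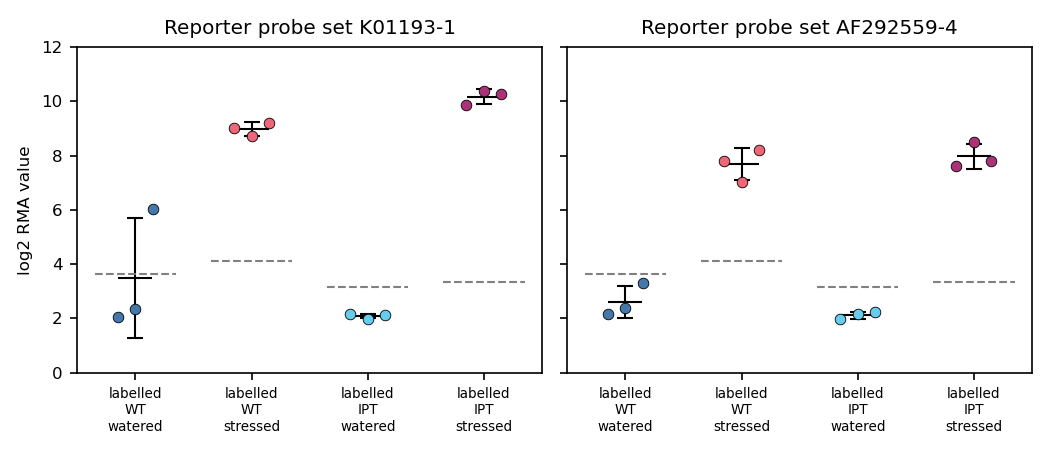
Log2 RMA values of 2 reporter probe sets by labelled group; points are arrays, black marks the mean ± SD of 3 arrays, and dashed lines the background level of each group. The arrays labelled WT_stressed (mean 8.98) and IPT_stressed (10.16) lie above background for RPTR-Os-K01193-1_at, and the arrays labelled IPT_watered (2.08) do not.

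The array controls separated the labelled genotypes. The Bio spike-in probe sets, added in known amounts after RNA isolation, averaged 10.9 ± 0.22 in WT_watered and 11.8 ± 0.26 in WT_stressed, against 8.42 ± 0.23 in IPT_watered and 8.45 ± 0.29 in IPT_stressed. The 3' GAPDH probe set exceeded the 5' one by 5.99 ± 1.05 and 6.90 ± 0.50 in the arrays labelled wild type and by 3.64 ± 0.17 and 3.86 ± 0.48 in those labelled IPT, in the same order of water conditions. The probe set for 18S rRNA averaged 4.83 in WT_watered (3.84 to 5.46), 5.87 in WT_stressed (4.28 to 6.78), 9.46 in IPT_watered (7.18 to 10.91) and 8.48 in IPT_stressed (7.96 to 9.45).

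**Figure D2:**
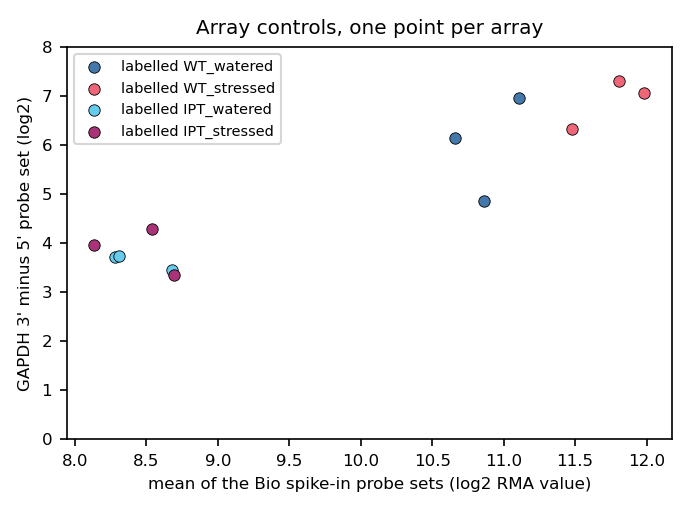
Mean of the Bio spike-in probe sets (x, log2 RMA value) against the difference between the 3' and 5' GAPDH probe sets (y, log2), 1 point per array. The 6 arrays labelled wild type lie at higher values of both measures than the 6 labelled IPT.

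The first comparison set WT_stressed against WT_watered and addresses the response of wild-type leaves to withheld water. OsSPX2, an SPX-domain protein of phosphate signalling, fell by 3.30 on the log2 scale (SE 0.55, adjusted p = 0.0374), from 7.40 ± 0.80 to a level at background, which makes it at least 9.83-fold lower. ARF9, an auxin response factor, fell by 1.13 (SE 0.19, adjusted p = 0.0374), and BADH, a betaine aldehyde dehydrogenase, fell by 0.73 (SE 0.13, adjusted p = 0.0420). The other named falls were PSS2, LIC, a zinc finger protein of brassinosteroid signalling, the locus LOC4342399, JMJ705, a histone H3 lysine demethylase, ITPase, the topoisomerase TOP3B and the replication factor OsRFC2, with changes of -1.17, -0.94, -0.87, -0.86, -0.76, -0.70 and -0.68 in that order. PSS2, LIC and JMJ705 reached background under stress and were at least 2.22-fold, 1.43-fold and 1.64-fold lower. Of genes with a protein name, 0 rose and 10 fell in limma's test.

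No list member passed over all genes in this comparison, yet camera placed 7 of 29 lists above the other genes. With 1 probe set per gene the median change was -0.18, so a list can lie above the other genes without rising. Over all probe sets the median was 0.12 for those with a mean under 5 and -0.28 for brighter ones. Whether signal level placed these 7 lists above was not tested. The pathogenesis-related list had the smallest p (13 genes, 10 of them higher, median 0.68, adjusted p = 2.48e-05, and adjusted p = 0.104 with an estimated correlation). Its member Cht11, a chitinase, had a change of 1.69 (SE 0.39, adjusted p = 0.0743), and 1 member passed when adjusted over the list alone. The diterpenoid phytoalexin genes, which make antimicrobial diterpenes, had 10 of 12 members higher (median 0.45, adjusted p = 0.00130, and adjusted p = 0.425 with an estimated correlation). All 3 ethylene synthesis genes were higher (adjusted p = 0.0407, and adjusted p = 0.250 with an estimated correlation), led by OsACO1 at 1.19 (SE 0.70). The 6 type-A response regulators, which are induced by cytokinin, had a median of 0.39 (adjusted p = 0.0404, and adjusted p = 0.425 with an estimated correlation), and 5 of the 6 were higher with other scalings. Neither of these 2 lists, nor the diterpenoid list, had a member passing when adjusted over the list alone.

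For nitrogen assimilation (16 genes, adjusted p = 0.00130, and adjusted p = 0.104 with an estimated correlation) the median was 0.10, and -0.0035 with array medians equal; the members with the smallest p were ammonium transporters, of which AMT3-3 at 1.26 (SE 0.27, adjusted p = 0.0626) passed when adjusted over the list alone. The jasmonate list (38 genes, adjusted p = 0.0319, and adjusted p = 0.425 with an estimated correlation) had a median of 0.018, and -0.086 with array medians equal, and 1 member passed when adjusted over the list alone. JAZ2, a repressor of jasmonate signalling, had the largest change in it, 5.40 (SE 1.18, adjusted p = 0.0662); it read 7.13 on WT_watered replicate 3 and 1.99 and 2.17 on the other 2 arrays of that group. The 30 cell wall loosening genes (adjusted p = 0.0139, and adjusted p = 0.250 with an estimated correlation) had a median of 0.022, and -0.065 after quantile normalization and -0.082 with array medians equal, and 0 members passed when adjusted over the list alone.

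Lists of water-deficit genes had 0 members called here. All 9 genes of ABA metabolism and PP2C had negative values (median -0.37, camera adjusted p = 0.479), the 14 drought regulators had a median of -0.29 (camera adjusted p = 0.954), and 4 of the 8 LEA and dehydrin genes were higher (camera adjusted p = 0.488); 0 members of these passed when adjusted over the list alone. Adjusted over the list alone, 3 of 36 auxin response genes and 1 member each of cytokinin metabolism, antioxidant enzymes, flowering regulators, NAC factors and the panicle and floral organ markers were lower, and 0 over all genes. OsNAC5, a stress-induced NAC factor, had a change of -1.07 (SE 0.30, adjusted p = 0.107), and OsDhn1, a dehydrin, -0.83 (SE 0.32, adjusted p = 0.188), where other probe sets gave -0.35 and -0.078.

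In limma's test 240 of 57194 probe sets passed, 90 higher and 150 lower, 71 of them with at least 2-fold change. The share called higher was 37.5%, against 12.1% of 848 with array medians equal, which moved the median change of all probe sets by -0.10, and 52.4% of 429 after quantile normalization; it was 66.7% of 111 with the trend and robust options, 72.2% of 18 with array weights and 68% of 25 with the GAPDH difference as a covariate. Among called probe sets with a mean under 5, 60.5% were higher, and among brighter ones 12.9%. The groups did not overlap for 18.1% of probe sets, where chance gives 10%. Every array moved the count by over 1.5 times when left out: it was 81, 80 and 46 without WT_watered replicates 1, 2 and 3, and 979, 130 and 2314 without WT_stressed replicates 1, 2 and 3; it was 2 when only these 6 arrays were fitted. Each of the 10 named genes lost its call without at least 1 array, and without WT_watered replicate 3 OsSPX2 alone was still called.

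The second comparison set IPT_stressed against IPT_watered. Cht11 rose by 2.37 on the log2 scale (SE 0.39, adjusted p = 0.0426), from 8.18 ± 0.50 to 10.55 ± 0.71. AMT3-3, an ammonium transporter, rose by 1.71 (SE 0.27, adjusted p = 0.0293) and NH3, a homologue of the salicylate receptor NPR1, by 1.33 (SE 0.19, adjusted p = 0.0163), for which another probe set gave 0.58. HCT1 rose by 1.19 (SE 0.20, adjusted p = 0.0408). OsSPX2 fell by 3.32 (SE 0.55, adjusted p = 0.0408), from 7.18 ± 0.81 to 3.86 ± 0.33. These 5 were all the genes with a protein name that passed.

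Camera placed 3 lists above and 4 below the other genes. The 26 ribosomal protein genes had the smallest p, with 24 higher and a median of 0.68 (adjusted p = 4.21e-08, and adjusted p = 0.384 with an estimated correlation), although 0 members passed over all genes or adjusted over the list alone; RPL11 had a change of 1.02 (SE 0.32) and RPL9 of 0.95 (SE 0.28). All 12 diterpenoid phytoalexin genes were higher (median 0.45, adjusted p = 1.81e-04, and adjusted p = 0.370 with an estimated correlation), 0 called over all genes and 6 adjusted over the list alone; CPS4, a diterpene cyclase at background when watered, had 2.74 (SE 0.61, at least 3.48-fold) and CYP99A2 1.52 (SE 0.41). Of 13 pathogenesis-related genes, 1 passed over all genes and 6 adjusted over the list alone (median 1.02, adjusted p = 0.00704, and adjusted p = 0.370 with an estimated correlation), with Cht2, a chitinase, at 2.37 (SE 0.51) and 0.65 to 2.89 over its probe sets. AMT3-3 was the 1 of 16 nitrogen assimilation genes to pass over all genes, and 3 rose when adjusted over the list alone (camera adjusted p = 0.316).

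The 9 genes of ABA metabolism and PP2C lay below the other genes (median -0.53, 8 lower, adjusted p = 0.00136, and adjusted p = 0.370 with an estimated correlation); 0 passed over all genes and 1 adjusted over the list alone. OsPP2C06, a protein phosphatase of ABA signalling, had a change of -1.28 (SE 0.22, adjusted p = 0.0525). The LEA and dehydrin genes had a median of -0.33 (adjusted p = 0.0233, and adjusted p = 0.370 with an estimated correlation), with 0 passing over all genes and 1 adjusted over the list alone, and OsDhn1 at -1.35 (SE 0.32), for which another probe set gave 0.12. All 6 circadian clock genes (median -0.29) and all 5 flowering regulators (median -0.55) were lower, both with adjusted p = 0.0450, and adjusted p = 0.370 with an estimated correlation; 0 members of either passed over all genes or adjusted over the list alone.

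Outside the called lists, the WRKY factors had 2 of 6 members, the antioxidant enzymes 1 of 13, the jasmonate list 1 of 38 and ethylene synthesis 1 of 3 higher when adjusted over the list alone, and the gibberellin list 1 of 9 lower, with 0 over all genes in each. Those of WRKY factors with the smallest p, WRKY62 and WRKY76, had 2.71 (SE 0.69) for either gene, and CatA, a catalase, had 1.61 (SE 0.36, adjusted p = 0.131), with 1.33 to 2.21 over its probe sets. The 7 chlorophyll synthesis genes were all higher, with a median of 0.56 and camera adjusted p = 0.152. JAZ2 had 5.22 (SE 1.18, adjusted p = 0.131).

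In limma's test 101 probe sets passed, 93 higher and 8 lower, and 97 of these differed at least 2-fold. The groups did not overlap for 20.3% of probe sets, where chance gives 10%. The count was 31, 31, 37 and 33 without IPT_watered replicates 1 and 2 and IPT_stressed replicates 1 and 3, and 816 without IPT_stressed replicate 2; with a minimum mean of 5 it was 3. With array weights it was 4970, of which 58.5% were higher against 92.1%, and without IPT_watered replicate 3 it was 143, of which 92 were higher and 51 lower. Each of the 5 named genes lost its call without at least 3 of the 6 arrays in turn, IPT_stressed replicate 3 and IPT_watered replicate 1 among them, and HCT1 was called only without IPT_stressed replicate 2.

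The difference between the 2 stress effects was tested directly, as the question whether PSARK::IPT leaves respond otherwise than wild-type leaves. NH3 had the smallest p, with a difference of 1.42 (SE 0.27, adjusted p = 0.201), followed by OsPDIL5-1, a protein disulfide isomerase, at 1.13 (SE 0.23), HCT1 at 1.32 (SE 0.28), oRrp46 at 1.21 (SE 0.26) and Cyt-RPEase at 1.38 (SE 0.30); none passed. In camera 4 lists passed. The median difference was 0.21 with 1 probe set per gene and 0.32 with a minimum mean of 5, against -0.066 over all probe sets. Whether signal level placed these 4 lists above or below the other genes was not tested. The 26 ribosomal protein genes lay above the other genes, 25 of them with a positive difference (median 0.84, adjusted p = 0.00207, and adjusted p = 0.624 with an estimated correlation). The LEA and dehydrin genes (median -0.19, 7 of 8 not positive, adjusted p = 0.391 with an estimated correlation), cell wall loosening genes and dividing cell markers lay below, each with adjusted p = 0.0201. For the last 2 the adjusted p was 0.306 with an estimated correlation, and their medians of -0.059 and -0.069 were 0.074 and 0.064 with array medians equal and 0.066 and 0.031 after quantile normalization. In each of the 4 lists 0 members passed over all genes or adjusted over the list alone; of the antioxidant enzymes 1 of 13 was higher adjusted over the list alone and 0 over all genes.

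Limma called 0 of 57194 probe sets for this difference, with 8178 at an unadjusted p under 0.05. Limma's trend and robust options called 5, the fit with array weights 0, and the fit without IPT_stressed replicate 2 called 40. Equal array medians moved the median difference of all probe sets by 0.13.

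The 2 stress effects, which share no arrays, were also set side by side. OsSPX2 fell in both. Across 17905 genes, which are not independent replicates, their Pearson correlation was 0.386 and the Spearman correlation 0.151; across all 57194 probe sets they were 0.257 and 0.0374. In both comparisons 5 genes were called higher and 2 lower, where independent lists would share 0.0190 and 0.0163, and 0 genes were called in opposite directions against 0.170. Singled out after their values were seen, LOC4335304 rose by 3.02 in wild type and 2.66 in PSARK::IPT (SE 0.37 for both) and LOC4340325 by 3.29 and 4.23 (SE 0.39 for both). Neither has a protein name in the annotation used. The watered means of LOC4340325, 3.30 and 2.37, lay below the background levels of 3.62 and 3.15. Its stressed means were 6.59 and 6.60, so its 2 changes are not to be compared in size.

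**Figure D3:**
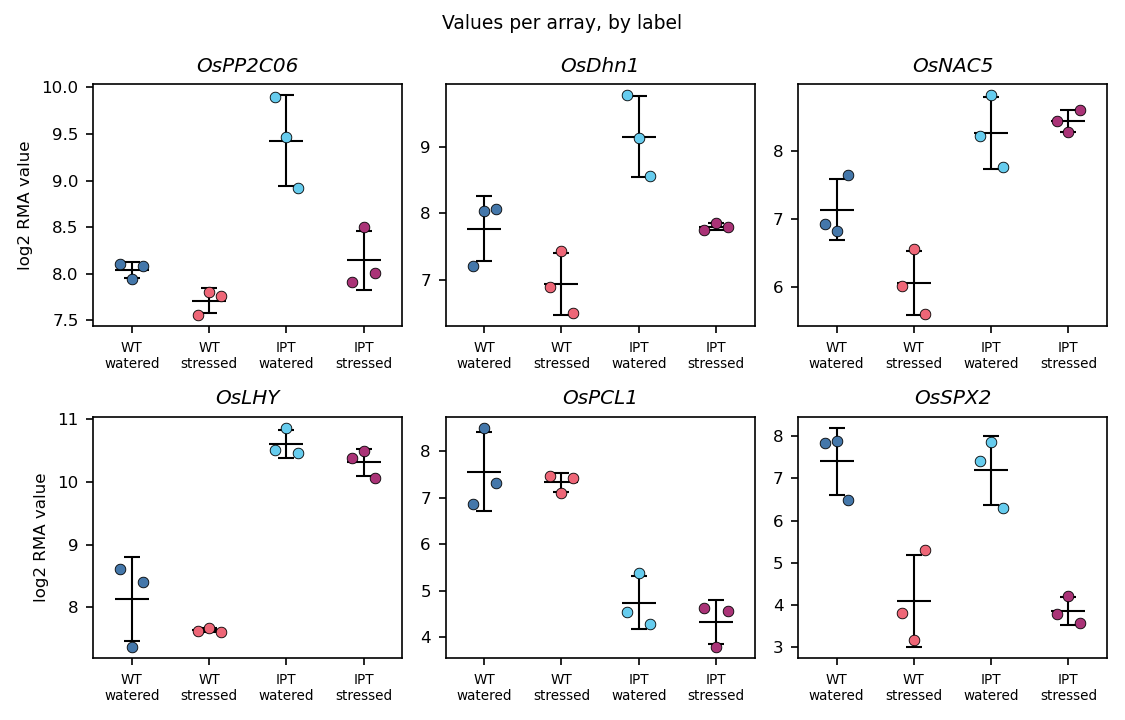
Log2 RMA values of 6 genes by labelled group; points are arrays and black marks the mean ± SD of 3 arrays. OsSPX2 is lower on the arrays labelled stressed, OsLHY and OsPCL1 part the labelled genotypes, and OsPP2C06 and OsDhn1 have their highest group means, 9.43 and 9.15, on the arrays labelled IPT_watered.

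The labelled genotypes were compared next, first under full watering. OsVIT1.2, a vacuolar iron transporter, rose by 3.77 on the log2 scale (SE 0.45, adjusted p = 3.20e-04), from 4.88 ± 0.25 in WT_watered to 8.65 ± 0.50 in IPT_watered. OsLHY, a morning-phased clock factor, rose by 2.49 (SE 0.27), and OsPCL1 and OsPRR1, clock genes with evening phase, fell by 2.82 (SE 0.40) and 0.78 (SE 0.21); a second probe set of OsLHY gave -0.10. Of the 6 genes of the clock list, which includes OsLHY and OsPRR1, 1 was called higher and 1 lower by either count, over all genes or adjusted over the list alone (camera adjusted p = 0.630); OsGI, OsPRR73, OsPRR95 and OsPRR37 did not pass, with changes of 0.53, 0.25 (another probe set 1.54), 0.11 and 0.068. Pi21, a blast resistance locus, fell by 4.43 (SE 0.96), MT2C, a metallothionein, by 2.80 (SE 0.88) and OsZIP4, a zinc transporter, by 2.45 (SE 0.44). Hd3a, the rice florigen, rose by 2.17 (SE 0.41).

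The remaining named rises were IMCEL2 (2.94, at least 7.32-fold), the proteasome subunit OsRPT1b (2.90), the ammonium transporter AMT1 (2.59), the beta-glucosidase BGLU36 (2.48), the homeodomain factor Hox22 (2.47), the inositol phosphate synthase INO1 (2.33), OsPP2C68 (2.32) and the aquaporin PIP1-1 (2.21). The remaining named falls were CSTLP4 (-2.36), the trehalose phosphatase OsTPP1 (-2.16), the vacuolar aquaporin TIP4-1 (-2.10), NH3 (-2.02), the heat stress factor HSF03 (-2.01) and BBD1 (-1.88). For NH3 another probe set gave 0.11, and other probe sets gave 0.45 for IMCEL2, 0.64 for AMT1, 0.47 for BGLU36, -1.47 for Pi21, -1.57 for MT2C and -0.98 for TIP4-1.

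When watered, 2635 of all 17905 genes were called higher and 1022 lower, and the list counts are to be read beside these shares. Camera passed 0 of 29 lists. Of the 9 genes of ABA metabolism and PP2C, 4 rose and 0 fell both over all genes and adjusted over the list alone (median 0.68, camera adjusted p = 0.108), with OsPP2C68 at 2.32, OsPP2C09 at 1.45 (SE 0.34), OsPP2C06 at 1.39 (SE 0.22) and OsABA8ox2, an ABA-degrading enzyme, at 0.58 (SE 0.18). Of 14 drought regulators 4 rose and 1 fell, over all genes and adjusted over the list alone: OsbZIP23, an ABA-responsive bZIP factor, rose by 1.47 (SE 0.35) and DREB2B by 1.07 (SE 0.24), and OsTPP1 fell. OsNAC5 rose by 1.13 (SE 0.30), but the mean of its probe sets gave -0.15. Among LEA and dehydrin genes 1 of 8 rose over all genes and 2 adjusted over the list alone; this was OsDhn1, at 1.39 (SE 0.32), for which another probe set gave -0.52. Of 25 aquaporins 7 rose and 1 fell over all genes, and 11 rose and 2 fell adjusted over the list alone (median 0.44). Of 16 nitrogen assimilation genes 5 rose and 2 fell by either count (median 0.59), of 33 sucrose and starch genes 6 rose and 0 fell by either count, and of 45 heat shock genes 7 rose and 1 fell by either count (median 0.31).

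In the hormone lists, cytokinin metabolism had 1 of 13 genes higher and 3 lower (2 and 3 adjusted over the list alone), with LOGL7, a cytokinin-activating enzyme, rising by 1.95 (SE 0.28) and another probe set at 0.96. The brassinosteroid list had 1 of 12 higher and 1 lower (1 and 2 adjusted over the list alone), jasmonate 2 of 38 higher and 3 lower by either count, gibberellin 1 of 9 higher and 2 lower by either count, and auxin response 3 of 36 higher and 4 lower (4 and 4 adjusted over the list alone). SLR1, the gibberellin repressor, fell by 1.23 (SE 0.28). Of 7 photosynthesis genes 1 rose (2 higher and 1 lower adjusted over the list alone), RCA, Rubisco activase, by 0.72 (SE 0.15), with 0.71 to 2.31 over its probe sets. Of 6 genes of chlorophyll breakdown and senescence 1 rose and 0 adjusted over the list alone. Among 11 panicle and floral organ markers 3 rose and 1 fell by either count, OsMADS1 by 1.20 (SE 0.24), and 0 of 3 anther markers passed. Of 13 antioxidant enzymes 1 rose and 1 fell (3 and 1 adjusted over the list alone), of 8 NAC factors 2 rose (2 higher and 1 lower adjusted over the list alone), and by either count 2 of 6 WRKY factors and 1 of 5 flowering regulators rose, 1 of 6 type-A response regulators fell, and 4 of 51 dividing cell markers rose and 3 fell. All 6 type-A response regulators had negative values (median -0.56, camera adjusted p = 0.144, and adjusted p = 0.795 with an estimated correlation). Of 30 cell wall loosening and 12 diterpenoid phytoalexin genes 1 each rose, and 0 adjusted over the list alone.

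In limma's test 10981 probe sets passed, 5889 higher and 5092 lower, 3503 of them with at least 2-fold change, and 0 of 29 lists passed in camera. The share called higher was 53.6%, against 69.8% of 10228 with array medians equal and 47.3% of 16912 with array weights, and the groups did not overlap for 42.4% of probe sets, where chance gives 10%. Among called probe sets with a mean under 5, 40.5% were higher, and among brighter ones 73.7%; of the genes called, 2635 were higher and 1022 lower. Beside all these genes, the difference between the 3' and 5' GAPDH probe sets had a change of -2.35, and with it as a covariate 39 probe sets passed, and the median standard error of all probe sets was 0.319 in place of 0.173. The count was 7002 without WT_watered replicate 2, 6212 without IPT_watered replicate 1 and 5841 without IPT_watered replicate 2.

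Under withheld water, IPT_stressed was set against WT_stressed. OsRPT1b was at least 5.15-fold higher (change 3.43, SE 0.30, adjusted p = 2.05e-05), Hd3a rose by 2.99 (SE 0.41), AMT1 by 2.85 (SE 0.36) and OsLHY by 2.68 (SE 0.27), whose second probe set gave -0.20. Other probe sets gave 0.71 for AMT1, 0.031 for IMCEL2 and 0.11 for OsCKX11. OsCKX11, a cytokinin-degrading oxidase, rose by 2.69 (SE 0.69, adjusted p = 0.00880), from 6.28 ± 1.85 to 8.97 ± 0.64. Pi21 fell by 6.01 (SE 0.96, adjusted p = 5.94e-04, another probe set -2.70), OsPCL1 by 3.01 (SE 0.40) and OsACO1, an ethylene-forming oxidase, changed by -2.93 (SE 0.70).

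Other named rises were OsUGE-1 (2.72), an enzyme interconverting UDP sugars, the calcium exchanger CAX1a (2.72), HSP16.0 (2.71, but -0.77 with the GAPDH difference as a covariate), the metal chelate transporter OsYSL13 (2.62) and IMCEL2 (2.79, at least 3.56-fold). Other named falls were HSF03 (-2.51), OsTPP1 (-2.49), OsZIP4 (-2.16), OsSAPK9 (-2.08), a kinase of ABA signalling, BBD1 (-2.05), CSTLP4 (-2.04) and ROMT-17 (-1.88), an O-methyltransferase for which another probe set gave 1.03.

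Of all 17905 genes 6309 were called higher and 1739 lower here, and the list counts are to be read beside these shares. Camera placed 0 lists above the other genes. Of 45 heat shock genes 18 rose and 2 fell by both counts, over all genes and adjusted over the list alone (median 0.65, camera adjusted p = 0.400), HSF1 by 2.37 (SE 0.36). Of 25 aquaporins 10 rose and 4 fell over all genes and 11 and 5 adjusted over the list alone, with PIP2-4 at 2.61 (SE 0.44) and PIP1-1 at 2.57 (SE 0.35). Of 33 sucrose and starch genes 11 rose and 3 fell by either count, among them the sucrose synthase SUS4 at 1.27 (SE 0.19). Of 26 ribosomal protein genes 10 rose over all genes and 4 adjusted over the list alone (median 0.65), RPL7A by 1.05 (SE 0.23); with the GAPDH difference as a covariate RPL7A, RPL10A, RPS10 and RPS7, 4 of these, had -0.10, -0.082, -0.56 and -0.069. Of 13 antioxidant enzymes 5 rose and 1 fell over all genes and 7 and 1 adjusted over the list alone, the ascorbate peroxidase APX1 by 1.88 (SE 0.41). Of 14 drought regulators 5 rose and 3 fell by either count, and of 9 genes of ABA metabolism and PP2C 4 rose by either count, including the ABA receptor gene PYL11 at 1.27 (SE 0.28).

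Cytokinin metabolism had 4 of 13 genes higher and 4 lower by both counts, over all genes and adjusted over the list alone, and LOGL9 rose by 2.03 (SE 0.49). Jasmonate had 8 of 38 higher and 6 lower by either count, with OsJAR1, which conjugates jasmonate, at 2.23 (SE 0.30), and auxin response 9 of 36 higher and 8 lower by either count. Pathogenesis-related genes had 5 of 13 higher and 1 lower and diterpenoid phytoalexin genes 4 of 12 higher by either count. Of 8 NAC factors 2 rose and 1 fell (2 and 2 adjusted over the list alone), OsNAC5 by 2.37 (SE 0.30) with another probe set at -0.79, and of 6 WRKY factors 2 rose by either count, WRKY51 by 1.90 (SE 0.27). Chlorophyll synthesis had 2 of 7 genes higher and 1 adjusted over the list alone. Panicle and floral organ markers had 2 of 11 higher and 4 lower by either count, OsMADS1 at 2.19 (SE 0.24), and 0 of 3 anther markers passed by either count. By either count 4 of 12 brassinosteroid genes rose and 1 fell, 2 of 7 photosynthesis genes rose and 1 fell, 2 of 5 flowering regulators rose, 1 rose and 1 fell in each of the lists of 3 ethylene synthesis and 6 clock genes, and 1 each of 9 gibberellin genes and 6 type-A response regulators fell. All 6 type-A response regulators had negative values here too (median -0.59, camera adjusted p = 0.145, and adjusted p = 0.919 with an estimated correlation). Nitrogen assimilation had 4 of 16 higher and 1 lower (3 and 1 adjusted over the list alone), LEA and dehydrin 1 of 8 higher and 2 lower (0 and 2 adjusted over the list alone), and chlorophyll breakdown and senescence 1 of 6 higher (0 adjusted over the list alone).

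Camera placed 2 lists below the other genes. With 1 probe set per gene the median change was 0.31, so a list can lie below the other genes without falling. Over all probe sets the median was -0.28 for those with a mean under 5 and 0.52 for brighter ones. Whether signal level placed these 2 lists below was not tested. Of 30 cell wall loosening genes 3 rose and 8 fell over all genes, 2 and 7 adjusted over the list alone (adjusted p = 0.00359, and adjusted p = 0.395 with an estimated correlation); the median of -0.22 was 0.0046 with array medians equal and 0.028 after quantile normalization. Among the members with the smallest p, EXPB11, an expansin, lay at background in both groups, and EXLA3, an expansin-like gene, was at least 2.42-fold higher. Of 51 dividing cell markers 7 rose and 7 fell, 7 and 3 adjusted over the list alone (adjusted p = 0.0195, and adjusted p = 0.502 with an estimated correlation); the median of -0.17 was 0.057 with array medians equal, and the members with the smallest p were the kinesins KIN13A at 1.61 (SE 0.20, another probe set 3.10) and KIN7C at 1.16 (SE 0.22), which are motor proteins also active outside division.

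**Figure D4:**
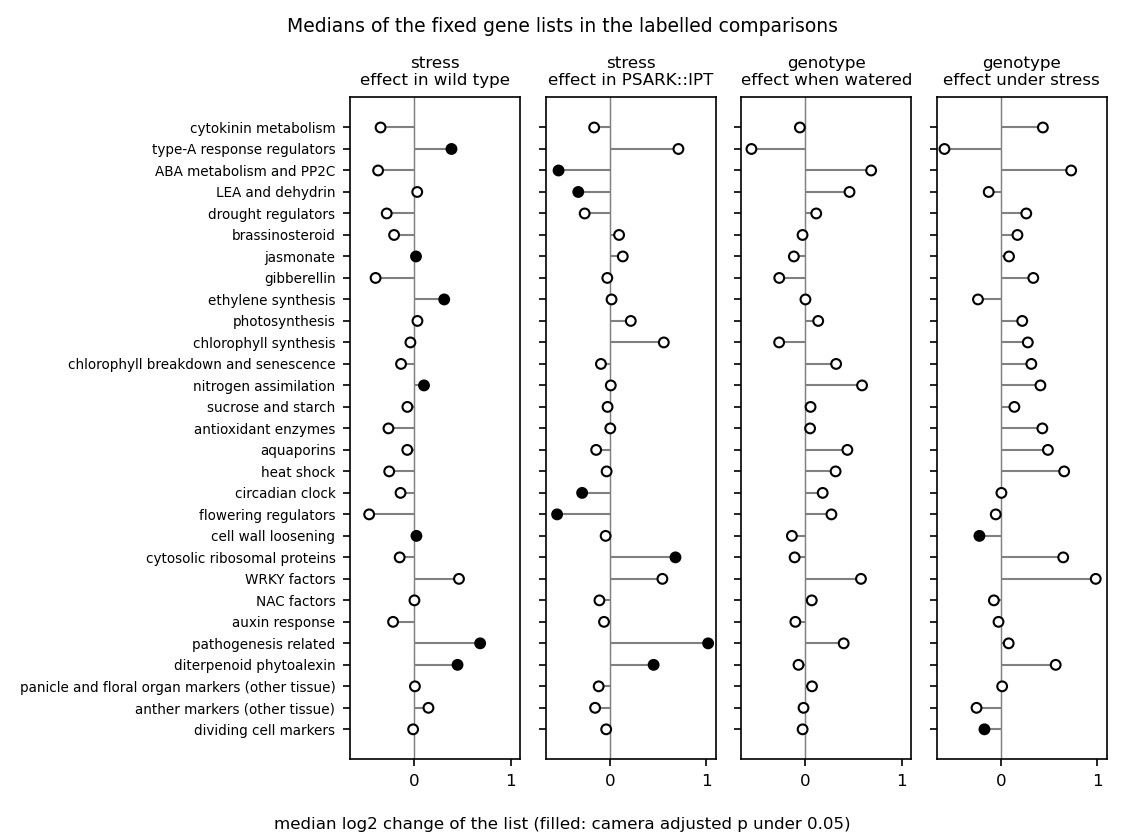
Median log2 change of each of 29 gene lists in the 4 comparisons between labelled groups; filled points have a camera adjusted p under 0.05. Of the water-deficit lists, ABA metabolism and PP2C has its lowest median, -0.53, in the stress comparison labelled PSARK::IPT and a median of 0.68 between genotypes when watered.

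In limma's test 26357 probe sets passed, 11065 higher and 15292 lower, 7328 of them with at least 2-fold change, and the groups did not overlap for 55.4% of probe sets against 10% by chance. The median change of all probe sets was -0.16; equal array medians moved it by 0.23 and quantile normalization by 0.12, and the share called higher went from 42.0% to 70.3% of 20880 and 48.2% of 15409. Among called probe sets with a mean under 5, 22.2% were higher, and among brighter ones 87.4%; of the genes called, 6309 were higher and 1739 lower. Beside all these genes, the difference between the 3' and 5' GAPDH probe sets had a change of -3.04, and with it as a covariate 129 probe sets passed, with a median standard error of 0.388 in place of 0.173. With a minimum mean of 5, the count was 7634.

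The genotype effects in the 2 water conditions, which share no arrays, had a Pearson correlation of 0.746 across genes. Both effects called 2392 genes higher and 550 lower, where independent lists would share 928 and 99.3, and 11 genes had opposite calls against 616. OsLHY, AMT1, OsRPT1b and IMCEL2 were among the named rises of both, and Pi21, OsPCL1, OsZIP4, OsTPP1, HSF03, CSTLP4 and BBD1 among the named falls of both. The array controls also parted the labelled genotypes in both water conditions, with changes of the GAPDH difference of -2.35 and -3.04. A shared technical gap could give such agreement too, and whether it did was not tested.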

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

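The tests of the reporter signal and of single arrays were chosen after the result was seen; the counts over other splits of the arrays were planned, except that for the probe sets of the difference between stress effects.

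Of the 4 reporter probe sets that ranged over more than 2 on the log2 scale, none of them part of the comparisons, 3 were called higher on arrays labelled stressed in at least 1 labelled genotype, 2 of them in both. RPTR-Os-K01193-1_at changed by 5.50 (SE 0.76) in the stress comparison labelled wild type and by 8.08 (SE 0.76) in that labelled PSARK::IPT, and RPTR-Os-AF292559-4_s_at by 5.07 and 5.86 (SE 0.34 for both). The watered means of both lay below background, so the folds are lower bounds: at least 41.0-fold and 129-fold for the first and at least 16.7-fold and 28.3-fold for the second. RPTR-Os-J01636-1_at changed by 1.17 (SE 0.18) in the wild-type comparison, from 5.20 to 6.37, where the Bio spike-in probe sets went from 10.9 to 11.8 and the background from 3.62 to 4.10; it read 3.35 and 3.32 on the arrays labelled IPT, where the spike-ins were lower too.

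Explanations of the K01193 and AF292559 signals were weighed with 31 water-deficit genes (ABA, LEA and drought lists together) as a measure of water status. The sources used here do not say whether the PSARK::IPT plants carry these sequences. The reading of 8.98 on the arrays labelled WT_stressed, against a background of 4.10, speaks against correct labels with the sequence in transgenic plants alone. Target from such plants on those arrays, or a binding rice transcript not tied to water deficit, could give that reading too. Neither was tested. A rice transcript induced by water deficit that binds the reporter probes would need a water-deficit response in the labelled stress comparisons, but the 31 genes had medians of -0.27 and -0.38 there, with 0 of 31 called, at percentiles 0.27 and 0 of 10000 random lists matched on signal, which speaks against it although such lists treat genes as independent. An exchange of the labels of the WT_stressed and IPT_watered arrays stays open: it would put the reporter on all transgenic arrays if these plants carry it, and the water-deficit genes then could be expected to differ between WT_watered and IPT_watered, where their median was 0.46, at percentile 100 of the random lists, with 23 of 31 higher, although none of the 3 lists passed there in camera, which compares them with other genes (adjusted p = 0.108 for ABA, 0.831 for LEA and 0.659 for drought, and 0.795, 0.923 and 0.795 with an estimated correlation). The array controls of the same groups differed too (GAPDH difference 5.99 and 3.64, Bio spike-ins 10.9 and 8.42, 18S rRNA 4.83 and 9.46). Between WT_stressed and IPT_stressed the gaps were larger for GAPDH (6.90 and 3.86) and the spike-ins (11.8 and 8.45) and smaller for 18S rRNA (5.87 and 8.48). The water-deficit genes had a median of 0.18 there, at percentile 55.4, no shift beyond the random lists. So their shift did not follow the GAPDH and spike-in gaps. It did have the same order as the 18S rRNA gap, larger when watered, so a technical cause stays open. Under the exchange the arrays labelled WT_stressed and IPT_stressed would hold the other stress comparison, that of PSARK::IPT plants. No size was set for that response, so the value does not decide on the exchange. The exchange stays a hypothesis and no sample was regrouped. The difference between the stress effects would be the same number under it.

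Replicate 3 of WT_watered stood towards the stressed arrays. Of 21 probe sets parting the other 5 watered arrays from the 6 stressed arrays by at least 1 on the log2 scale, 17 (81.0%) had this array beyond all 5 on the stressed side, and its median position was 0.31 of the way. Set against 4 watered arrays at a time, replicate 3 never among the references, the share was 81.0% to 88.2% for this array and 14.3% to 52.9% for the other watered arrays. Some target from reporter-carrying plants on this array may account for that, and no biological explanation was tested. RPTR-Os-K01193-1_at read 6.03 on this array. RPTR-Os-AF292559-4_s_at read 3.29, against 2.17 and 2.38 on replicates 1 and 2 of the group. That value lay below the background of 3.62, so this second reporter does not show such target above background.

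The difference between the stress effects passed camera for 4 lists, at adjusted p of 0.00207 for ribosomal proteins and 0.0201 for LEA and dehydrin, cell wall loosening and dividing cell markers; none passed with an estimated correlation. Of 100 drawn splits, 36 gave at least 4 lists and the highest other gave 9. The splits mixed the labelled genotypes within each water condition, which puts genotype differences into both the contrast and the spread. They therefore do not measure chance alone, and chance is not excluded for these lists. For the count of 0 probe sets all 100 splits gave at least as many, which a count of 0 fixes in advance. The highest other gave 31.

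For the comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05. Probe-set counts were 240 against a highest other of 22 for the stress effect in wild type, 101 against 0 for PSARK::IPT, 10981 against 0 for genotype when watered and 26357 against 126 for genotype under stress, so that 1 split of 10 was as large each time. Counts of called lists were 7 against a highest other of 5 (1 of 10 splits), 7 against 10 (4 of 10), 0 against 6 (10 of 10) and 2 against 7 (6 of 10) in the same order. Every split reaches a count of 0, so the 10 of 10 was fixed in advance.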

How the results depend on the processing

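The GAPDH covariate was the one alternative chosen after the data were seen. Probe-set counts are given in the order stress in wild type (main 240), stress in PSARK::IPT (101), genotype when watered (10981), genotype under stress (26357) and difference (0), and where a comparison is not named its count stayed within 1.5 times. The replicate block, for numbers that did not meet the rule for pairs (median correlation of deviations 0.0936 for the same number and -0.0177 for other numbers, and 24 of 36 best matches with the same number, a hint from the data alone), gave 60 and 287 for the stress effects. A minimum mean of 5 gave 20, 3, 4248 and 7634, and 1 probe set per gene 42, 20, 3203 and 7413; fewer probe sets were tested in both. Quantile normalization gave 429, 56 and, for genotype under stress, 15409, and equal array medians 848 for stress in wild type. Trend and robust fitting gave 111 for stress in wild type and 5 for the difference, and array weights 18, 4970 and, for genotype when watered, 16912. Fitting only the groups compared gave 2 for stress in wild type. The GAPDH covariate gave 25 for stress in wild type, 39 for genotype when watered and 129 for genotype under stress. Over the 218 calls lost for stress in wild type, the median change was 0.84 before and 0.81 after and the median standard error 0.14 and 0.16, and 0% turned. Over the calls lost in the last 2, the median change went from 0.78 to 0.69 and from 0.73 to 0.65 and the median standard error from 0.18 to 0.32 and from 0.17 to 0.38, so larger standard errors and smaller changes both entered. Apart from these, the cause of a change was not tested.

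Leaving out each array in turn gave 46 to 2314, 31 to 816, 5841 to 10243, 19383 to 27565 and 0 to 40 probe sets. The correlation of the stress effects, 0.386, was 0.469 with a minimum mean of 5, 0.151 by Spearman's method and 0.248 to 0.492 with an array left out.

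With the GAPDH covariate NAC010 turned to -0.27 for genotype when watered, and for genotype under stress HSP16.0 turned to -0.77, RAB16D to 0.017, CHLH to -0.19, APX5 to -0.075, RPL7A to -0.10, RPL10A to -0.082, RPS10 to -0.56, RPS7 to -0.069 and NAC010 to -1.08; a further 178 calls of named genes, counted over all comparisons, no longer passed. The covariate itself parted the labelled genotypes. With it, the median standard errors of all probe sets were 0.319 for genotype when watered and 0.388 for genotype under stress. The turned values are given without errors of their own, so they do not settle a direction. With the mean of a gene's probe sets OsNAC5 turned to -0.15 for genotype when watered and CatB to 0.049 for genotype under stress. For genotype under stress fry, which tests a list by itself, gave the opposite direction to camera for cytokinin metabolism (adjusted p = 0.0203), brassinosteroid (adjusted p = 0.0329) and sucrose and starch (adjusted p = 8.01e-04). All 20 camera calls over the 5 comparisons were lost with an estimated correlation; fry lost 18 and added 13 in camera's direction besides the 3 opposite ones above, and the mean of a gene's probe sets lost 0 and added 1. The share of probe sets above background, 44.1% in WT_watered, 35.8% in WT_stressed, 53.8% in IPT_watered and 48.3% in IPT_stressed, limits what dim genes can show.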

Other observations

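The family scan and the test by quantile normalization were chosen after the data were seen; the test of RNA quality was planned before its result was seen.

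Camera tested 84 families in each of 5 comparisons. The auxin response factors (17 genes, median -0.52, adjusted p = 8.83e-04, and adjusted p = 0.281 with an estimated correlation) lay below other genes in the stress comparison labelled wild type. ARF9 fell and ARF14, ARF24 and ARF3 had changes of -0.91, -0.92 and -0.77. In the comparison labelled PSARK::IPT the 10 SAPK kinases, which act in ABA signalling, lay below other genes (median -0.42, adjusted p = 0.0194, and adjusted p = 0.702 with an estimated correlation), with OsSAPK7 at -0.91 (SE 0.33). Between genotypes when watered, 24 of 63 protein phosphatase genes rose and 3 fell (median 0.48, adjusted p = 0.0185, and adjusted p = 0.760 with an estimated correlation), OsPP2C32 by 2.01 (SE 0.32) and OsPP2C10 by 1.65 (SE 0.19). None of these families passed with an estimated correlation.

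Between genotypes under stress, 6 of 7 GF14 genes, which encode 14-3-3 proteins, rose (median 1.30, adjusted p = 0.0158, and adjusted p = 0.454 with an estimated correlation). Of 6 YABBY genes 4 fell (median -0.57, adjusted p = 0.0103, and adjusted p = 0.177 with an estimated correlation), and the 9 cellulose synthase genes had a median of -0.67 with 1 fall, that of CESA2, which lay at background in both groups (adjusted p = 0.0103, and adjusted p = 0.636 with an estimated correlation). The families described were picked from those that passed at the preset correlation. By stem, the others were GER, PHT and PT for stress in wild type, and GER, GRF, LAC, PHT, PP and PT for genotype under stress. For the difference of the stress effects they were CESA, GER, GRF, PHT, PT and SWEET. Families of different stems can share genes.

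The probe sets called between the labelled genotypes moved with signs of RNA or target quality. Against the labelled genotype, which stays open as untested, 2 technical explanations were weighed. If the labels were exchanged as in the hypothesis above, these comparisons would be between water conditions, so a water response stays open too. If quality were the cause, the change expected from slopes on the GAPDH difference within groups should follow the observed change across called probe sets; the correlation was 0.427 when watered and 0.411 under stress, between the bounds of 0.5 and 0.1 set beforehand. It fell to 0.084 and -0.013 without the WT_watered group, so it rests on that group and does not decide. After quantile normalization, which gives every array the same spread, 63.9% of the called probe sets were still called when watered and 48.3% under stress, so unequal spreads do not account for those and stay open for the rest. Quality and labelled genotype cannot be told apart here because both follow the same label.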
